A study of Mus musculus with 6 samples.

How the data were processed

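RNA was measured in cells sorted from the thoracic oesophagus of mice on high EpCAM, an epithelial surface protein. The sample titles call the untreated cells epithelial and the ibuprofen cells only oesophageal, a difference in wording that follows the treatment and is not explained. The mice carried Krt5-CreERT2:R26SmoM2/EYFP, written K5:Smo here. In this model tamoxifen switches on SmoM2, a constantly active form of the Hedgehog transducer Smoothened, in cells that express keratin 5. All 6 libraries were from 12 weeks after tamoxifen, 3 from untreated mice and 3 from mice given ibuprofen, an inhibitor of the cyclooxygenases, at 0.6 g per l in the drinking bottle. Per the labels' protocols, tissue was digested and sorted into lysis buffer, and libraries were made with the Ovation Solo RNA-seq system and read on an Illumina NovaSeq.

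The deposited values are CPM, reads of a gene scaled to each library's gene total, as the file headers name them, for 52636 gene IDs. The submitters' processing notes name STAR 2.5.3a, HTSeq, edgeR and Cell Ranger 3.1.0 with no role given, and the builds GRCm38 and mm10. The annotation release and any filter are not given in the sources used here. Each column summed to the same total, and no further scaling between libraries was visible in the values. The values fell on steps that a whole read number would give after scaling each library to a common total and rounding up. From these steps the reads assigned to genes were estimated as 6361297 to 8764370 per library. At least 99.82% of the values above 0 were returned exactly by this reading of the steps. In 3 simulated libraries made the same way the estimated totals were exact. No count model was fitted to the estimated reads, which were used only to describe depth and detection limits. A CPM listed as 0 is 0 reads on this reading of the steps. An expected count of up to 3 reads is still possible at such a value, or 0.342 to 0.472 CPM by library. These floors and the depth cover counting error only.

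Genes with a CPM of at least 1 in at least 3 of the 6 libraries were tested, 16684 in all. limma 3.58.1 in R 4.3.3 was run on log2(CPM + 1), with a mean-variance trend, without robust shrinkage and without a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are ibuprofen minus untreated on the log2(CPM + 1) scale, which understates the change of low genes. Errors of fold changes are standard errors (SE), and errors of CPM are standard deviations (SD) with n = 3. Nothing in the labels says whether libraries came from separate animals, so p-values measure only the spread between these libraries. In the library names, all untreated libraries share one code and all ibuprofen libraries another. What the codes mean is not given, and any batch they mark cannot be told apart from the treatment.

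The 32 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 22 in all, were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. The rule named the 10 largest and 10 smallest fold changes among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM. It left out predicted, clone-named and pseudogene symbols. It also named 15 fixed genes, up to 4 members with the smallest p of each list that was called or held a called gene, 1 or 2 members of other lists, and the most abundant markers of other cell types. The values of 1 gene that the rule names are not reported here. Where a symbol had several IDs, the one with the higher mean was used in lists. Shares per library were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Gene positions, lengths and GC content came from GENCODE annotation of GRCm38, in which 16651 of the tested IDs were found.

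The procedure was tested on simulated libraries of 3 against 3 with 100 genes changed per fold size, in which 16910 genes were tested. It called 49% of 2-fold and 86% of 4-fold changes, with 4 unchanged genes called. With no change simulated it called 0 genes. In the same simulation with 1 list lowered, 1 list was called. Simulated genes varied independently of each other, so this does not test the list calls against genes that vary together. Their variation followed a smooth trend on expression, with no scatter between genes and no differences between libraries in GC content. The shares of gene calls hold for such libraries and may differ in the real ones. Alternatives covered the pseudocount, the filter, the scaling, library weights, robust shrinkage, a block on replicate number, each library left out, and other list tests. Corrections for GC content and gene length were added after seeing the data.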

Results

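EpCAM-high cells of the thoracic oesophagus were profiled by RNA sequencing in K5:Smo mice 12 weeks after tamoxifen, with 3 untreated and 3 ibuprofen libraries. The estimated number of reads assigned to genes ranged from 6361297 to 8764370 per library, and 24414 to 27937 genes had a CPM above 0. The design holds 1 comparison, which asks how gene expression in these cells differed between mice that drank ibuprofen and mice that did not.

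Several chaperone genes fell with ibuprofen, while the Hedgehog target genes Gli1 and Ptch1 did not pass the test. Hsph1, a heat-shock co-chaperone of the HSP110 family, fell from 97.9 ± 2.9 to 39 ± 3.4 CPM (SD, n = 3), or 2.51-fold. Hspa5, the main chaperone of the endoplasmic reticulum (ER), fell from 1030 ± 47 to 598 ± 83.8 CPM. Among genes that rose, the sodium channel gene Scn3a went from 3.73 ± 1.51 to 23.5 ± 3 CPM and Greb1l from 8.34 ± 2.27 to 39.5 ± 7.85 CPM. In all, limma called 87 of 16684 tested genes, 50 higher and 37 lower with ibuprofen. At an unadjusted p under 0.05 there were 1963 higher and 1030 lower genes. The count was 4 without untreated replicate 1, 5 without untreated replicate 2, 456 without untreated replicate 3, 23 without ibuprofen replicate 1 (7 higher and 16 lower), 44 without ibuprofen replicate 3, 52 with no filter and 2462 with library weights. After correction for GC content it was 51 higher and 60 lower.

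**Figure D1:**
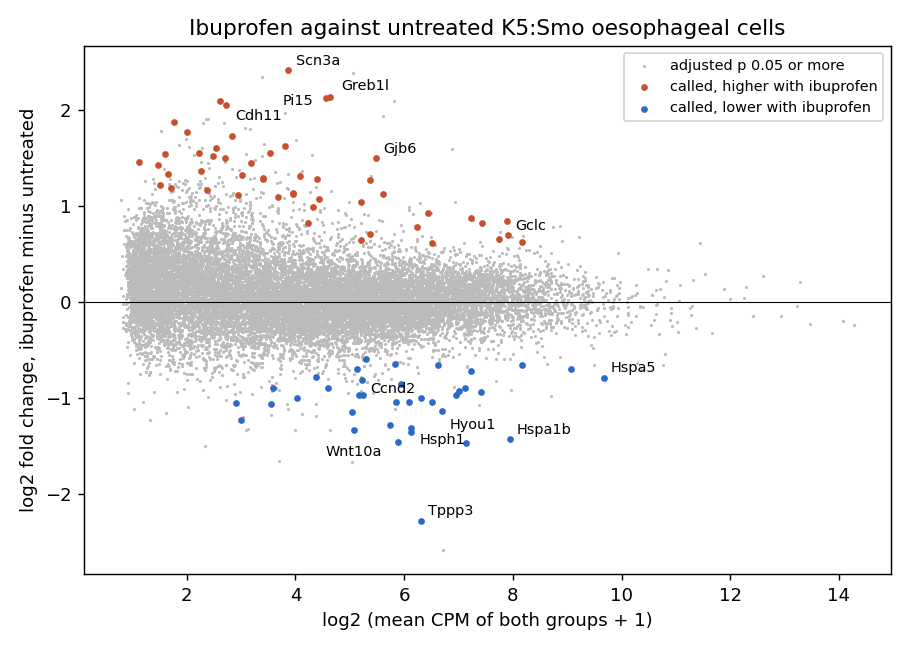
Log2 fold change (ibuprofen minus untreated) against log2 of the mean CPM plus 1 for the 16684 tested genes. Coloured points are the 50 genes called higher and the 37 called lower by limma; Scn3a at 2.41 and Tppp3 at -2.28 are the called genes farthest from 0.

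Scn3a (ENSMUSG00000057182, chromosome 2, 65457118 to 65567627, GRCm38) rose by 2.41 ± 0.23 log2 units (SE, limma adjusted p = 0.0028). Greb1l (chromosome 18, 10325177 to 10562940) rose by 2.13 ± 0.21 (limma adjusted p = 0.00316). Both stayed called under each of the 18 alternatives run on genes. Pi15 averaged 6.58 ± 0.301 CPM untreated and 38.6 ± 27.7 CPM with ibuprofen, with a limma adjusted p of 0.0492 and a call that held in 5 of the 18. Its ibuprofen replicates 1, 2 and 3 had 68.7, 14.2 and 33 CPM. Cdh11, a cadherin of mesenchymal cells, rose by 2.04 ± 0.27, from 1.48 ± 0.236 CPM to 15.1, 7.14 and 7.1 CPM in ibuprofen replicates 1, 2 and 3. Ibuprofen replicate 1 also stood apart in fibroblast markers, and without it the fold changes were 1.58 for Pi15, no longer called, and 1.71 for Cdh11, still called. Nrxn3 and Pclo, which encode synaptic proteins, rose by 1.76 ± 0.26 and 1.63 ± 0.25. Osbpl1a rose by 1.55 ± 0.27, Mtus2 by 1.55 ± 0.22 and Atp6v1b1, a subunit of the proton pump, by 1.51 ± 0.29. Gjb6, the gap junction gene connexin 30, rose from 21.7 ± 5.07 to 65.3 ± 26.3 CPM. The limma adjusted p of these last 7 genes lay between 0.0214 and 0.0487. Atp6v1b1 stayed called in 8 of the 17 alternatives that tested it. The 50 higher genes spanned a median of 61.6 kb of genome, against 15.9 kb for all tested genes, and 42 of them lay above that median. Across all tested genes Spearman's rho between fold change and span was 0.07, and between fold change and transcript GC content -0.32. Median GC content was 47.5% in the higher, 50.6% in the lower and 49.3% in all tested genes.

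Of the genes with the largest falls, Tppp3, a tubulin-binding protein gene (chromosome 8, 105467493 to 105471526), fell from 129 ± 48.1 to 27.3 ± 16.2 CPM, a log2 change of -2.28 ± 0.33 (limma adjusted p = 0.0221). Wnt10a, a Wnt ligand, went from 86.5 ± 28.2 to 30 ± 5.64 CPM. The cyclin D2 gene Ccnd2 fell from 121 ± 15.8 to 58.6 ± 11 CPM. Pcsk6, a proprotein convertase, fell by 1.23 ± 0.18, the ER chaperone gene Hyou1 by 1.13 ± 0.14, Bace2 by 1.07 ± 0.2 and Dagla, which makes the endocannabinoid 2-arachidonoylglycerol, by 1.05 ± 0.18. The limma adjusted p of these 6 genes after Tppp3 lay between 0.0171 and 0.0492. Bace2 stayed called in 9 of 18 alternatives. The heat-shock genes Hspa1a and Hspa1b fell by 1.47 ± 0.22 and 1.43 ± 0.2. Their sequences are nearly identical, so reads could be split between them, and the called gene model Gm20481 lies within Hspa1a. Another 5 called gene models, such as Gm10722, lie within 3000922 to 3035805 of chromosome 9, and reads shared among them leave their values uncertain.

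The unfolded protein response list, which holds ER chaperones and stress factors, was lower with ibuprofen by camera, though not in all its members. Of its 18 tested members 3 fell, 0 rose and 15 did not pass, and adjusted over the list alone 11 fell. The called members were Pdia6 (-0.92 ± 0.12), Hspa5 (-0.79 ± 0.12) and Manf (-0.85 ± 0.13). Creld2 had a log2 fold change of -1.16 ± 0.22 and a limma adjusted p of 0.0534. The stress factor genes Atf4 and Ddit3 were near 0, at -0.01 ± 0.11 and -0.04 ± 0.21. The 3 members with positive values were Chac1 (0.47 ± 0.31), Dnajb9 (0.04 ± 0.12) and Atf5 (0.04 ± 0.14). The list had a camera adjusted p of 2.36e-09 in limma, and an adjusted p of 0.141 with an estimated correlation. The list of immediate-early and heat-shock genes was lower too, with 3 of 21 fallen, 18 not past the threshold and 4 fallen adjusted over the list alone. The members that fell were Hsph1 (limma adjusted p = 0.00153), Hspa1a and Hspa1b (both 0.0221), all heat-shock genes. Hspa8, the constitutive HSP70 gene, had 1010 ± 30 CPM untreated and 792 ± 53 CPM with ibuprofen. In limma the camera adjusted p was 2.15e-07, against an adjusted p of 0.423 with an estimated correlation. In both lists the real split of the libraries gave a smaller camera p than the 9 other splits of the 6 libraries into 3 and 3.

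**Figure D2:**
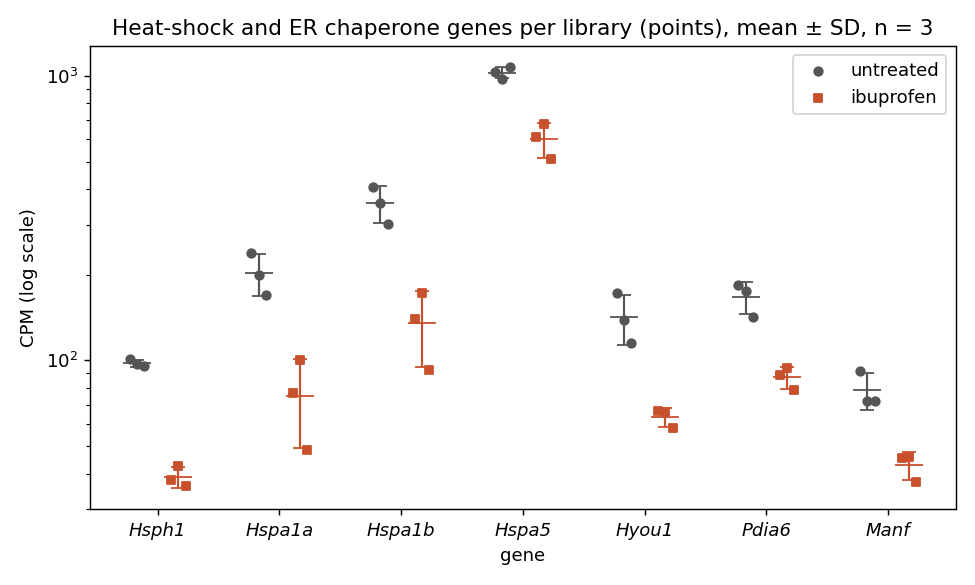
CPM on a log axis of 7 heat-shock and ER chaperone genes in each library, with the mean and SD of the 3 untreated and 3 ibuprofen libraries. In every gene shown the ibuprofen libraries lie below the untreated ones, for Hsph1 at a mean of 39 against 97.9 CPM.

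The list of NRF2 and xenobiotic response genes was higher with ibuprofen. Of 22 tested members 1 rose, 21 did not pass, and 6 rose adjusted over the list alone. The member that rose was Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, from 183 ± 15.7 to 298 ± 42.6 CPM (0.69 ± 0.12, limma adjusted p = 0.0397). Gsta3, a glutathione transferase, and the cystine transporter Slc7a11 had log2 fold changes of 0.82 ± 0.18 and 0.94 ± 0.22, and Ugt1a7c of 0.37 ± 0.1. In limma the camera adjusted p was 0.0165, and the adjusted p with an estimated correlation 0.423. Without untreated replicate 2 the camera adjusted p was 0.0537.

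The cell cycle and cholesterol biosynthesis lists were lower by camera with 0 members called by limma. In the cell cycle list 32 of 34 members had negative fold changes, with a median of -0.298. The members with the smallest p were Ccne1 (-0.68 ± 0.24), E2f1 (-0.7 ± 0.28), the replication helicase gene Mcm2 (-0.83 ± 0.33) and Cdc20 (-0.48 ± 0.19). The proliferation marker Mki67 had 960 ± 227 and 1010 ± 375 CPM. In cholesterol biosynthesis 21 of 22 members had negative fold changes, such as Dhcr7 (-0.58 ± 0.17), Mvk (-0.46 ± 0.19), Hsd17b7 (-0.34 ± 0.15) and Nsdhl (-0.33 ± 0.16). Adjusted over the list alone, 0 members of either list passed. The camera adjusted p in limma was 8.62e-06 for cell cycle and 0.000133 for cholesterol biosynthesis, and both had an adjusted p of 0.833 with an estimated correlation. Without ibuprofen replicate 3 the cell cycle list had a camera adjusted p of 0.721, and without ibuprofen replicate 1 cholesterol biosynthesis had 0.0804. In 6 of the 9 other splits of the libraries the cell cycle list had a smaller camera p than in the real one, and in 2 cholesterol biosynthesis did. Across lists, 8 of the 10 splits, the real one included, called at least 5 lists.

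Of 15 Hedgehog pathway genes 11 were expressed highly enough to be tested, and 0 of these passed. Gli1, a direct Hedgehog target, had 284 ± 46.8 CPM untreated and 264 ± 23.1 CPM with ibuprofen, and the receptor gene Ptch1 had 1680 ± 215 and 1940 ± 223 CPM. Smo had 294 ± 29.3 and 288 ± 8.87 CPM. Adjusted over the list alone 0 members passed, and the list had a median of 0.055 and a camera adjusted p of 0.962 in limma. The member with the smallest p was the co-receptor gene Cdon, at -0.44 ± 0.12. Hhip averaged 0.117 ± 0.202 and 0.1 ± 0.173 CPM, under the floor of 3 reads. The ligand genes Shh, Ihh and Dhh were also too low to be tested, at means of 0.05, 0.217 and 0.317 CPM untreated and 0.183, 0.183 and 1.13 CPM with ibuprofen.

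Genes of the prostanoid pathway, on which ibuprofen acts through cyclooxygenases, gave 0 calls among 19 tested members. Ptgs2, the inducible cyclooxygenase gene, had 468 ± 137 CPM untreated and 475 ± 56.3 CPM with ibuprofen, Ptgs1 had 6.15 ± 1.65 and 6.21 ± 0.928 CPM, and the receptor gene Ptger4 39.7 ± 5.15 and 41.2 ± 4.38 CPM. The members with the smallest p were the prostaglandin transporter gene Slco2a1 (1.11 ± 0.3) and Hpgds (1.31 ± 0.39). The list had a median of 0.07 and a camera adjusted p of 0.36 in limma.

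Keratin genes of the oesophageal epithelium gave no call. Krt5 had 3620 ± 439 CPM untreated and 2880 ± 225 CPM with ibuprofen, Krt14 2130 ± 432 and 1450 ± 121 CPM, both basal keratins. The suprabasal keratins Krt13 and Krt4 had 2310 ± 205 and 1910 ± 509 CPM, and 166 ± 47.8 and 153 ± 39.9 CPM. Epcam itself had 261 ± 26 and 259 ± 22.7 CPM. In the basal list, with a median of 0, Krt15 had the smallest p (-0.64 ± 0.13), and adjusted over the list alone 2 of 16 rose and 2 fell. In the differentiation list Krt1 had 1.37 ± 0.29, and adjusted over the list alone 2 of 20 rose and 3 fell, with a median of -0.004. Their camera adjusted p in limma was 0.535 and 0.354.

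Of 14 tested columnar and metaplasia genes 1 rose, the intestinal mucin gene Muc2. It went from 0.5 ± 0.15 to 3.53 ± 1.52 CPM (limma adjusted p = 0.0397), a level that rests on few reads. Its call held in 9 of the 14 alternatives that tested it, with log2 fold changes from 0.62 to 2.53. Muc2 reached 1 CPM only in the 3 ibuprofen libraries. It was thus untested at the filter of 5 CPM and with any ibuprofen library left out, so its call was not checked against that loss. Vil1, Agr2 and Muc5b had log2 fold changes of 0.89 ± 0.33, 0.73 ± 0.32 and 0.89 ± 0.4. Sox9, a regulator of columnar fate, had 95.9 ± 12.3 and 95.9 ± 23.4 CPM. Krt8 had 0.4 ± 0.173 and 2.71 ± 2.13 CPM, with 2.5, 4.95 and 0.7 CPM in ibuprofen replicates 1, 2 and 3. It was not tested because fewer than 3 libraries reached 1 CPM. The other untested members of the 30 listed averaged at most 1.52 CPM in either group (Krt18 with ibuprofen). The list had a median of 0.275 and a camera adjusted p of 0.107 in limma. In the p53 list 1 of 15 members rose, Trp53inp1, from 54.8 ± 9.67 to 93.9 ± 6.28 CPM (limma adjusted p = 0.0357). Fas, Phlda3 and Bax had log2 fold changes of 0.44 ± 0.15, -0.53 ± 0.21 and -0.45 ± 0.19, and the list a median of 0.026 and a camera adjusted p of 0.962.

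The other lists of programs held 0 called genes over all genes and missed the list test. Inflammatory mediators had a median of -0.063, a camera adjusted p of 0.0757 in limma and, adjusted over the list alone, 1 of 17 fallen, the NF-kB inhibitor gene Nfkbia (-0.52 ± 0.11). Wnt targets had a median of 0.204, with 2 of 12 risen and 1 fallen adjusted over the list alone, and Lgr5 at 1.04 ± 0.24 and Wif1 at 1.93 ± 0.44. Mesenchymal and matrix genes had a median of 0.203, with 4 of 16 risen adjusted over the list alone, Postn at 1.59 ± 0.39 among them. Relative to the untreated mean, the list's mean was 0.543 log2 units in ibuprofen replicate 1, 0.057 in replicate 2 and 0.154 in replicate 3. PPAR and fatty acid oxidation had a median of 0.107, with 3 of 20 risen adjusted over the list alone, Pparg at 0.87 ± 0.22 among them. Glycolysis and hypoxia had a median of -0.058, with 3 of 23 risen adjusted over the list alone and Bnip3 at 0.8 ± 0.16. The Notch list had a median of 0.062 and 1 of 9 risen adjusted over the list alone, Maml3 at 0.54 ± 0.12. Interferon-stimulated genes and antigen presentation had medians of -0.001 and -0.055, with Irf1 at -0.34 ± 0.12 and H2-D1 at -0.41 ± 0.13 and 0 passing adjusted over the list alone.

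**Figure D3:**
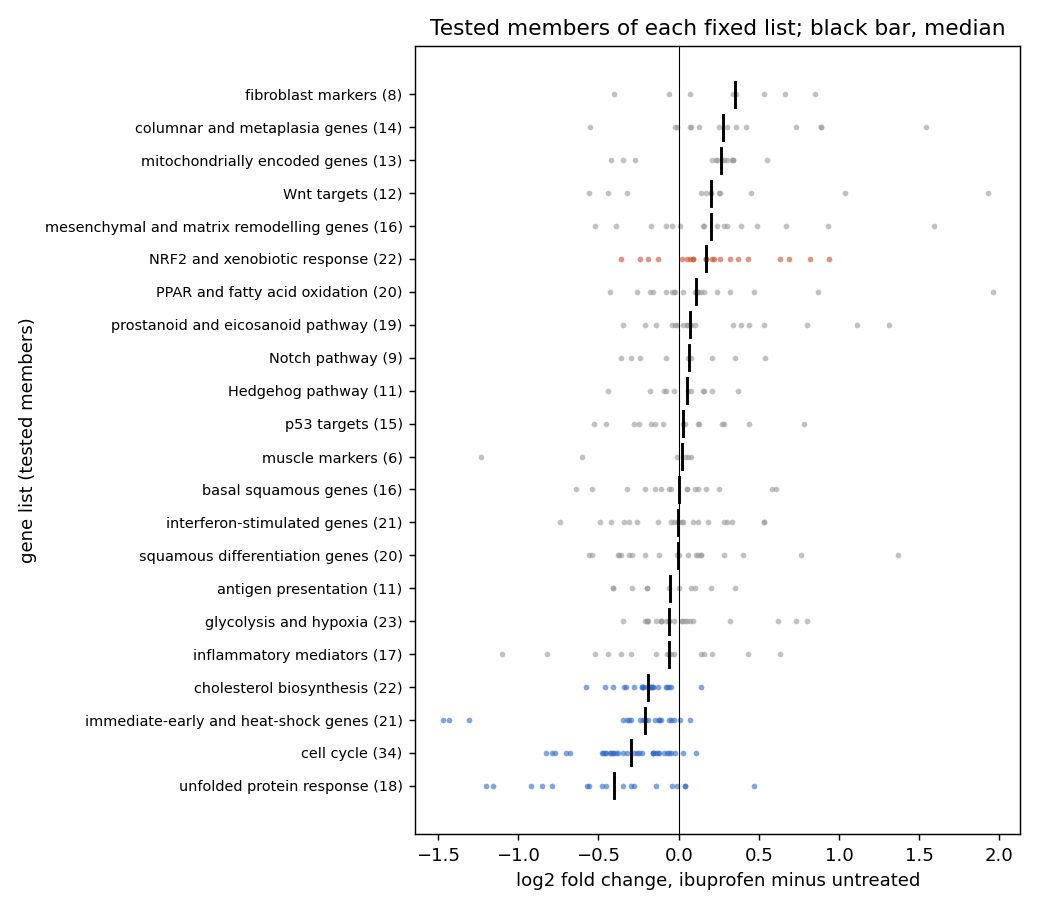
Log2 fold changes (ibuprofen minus untreated) of the tested members of the 22 tested lists, with the median of each list as a black bar. Blue lists were called lower and the red list higher by camera at its preset correlation, while 0 lists are called with an estimated correlation; the unfolded protein response has the lowest median, at -0.4.

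The lists of other cell types held 0 genes called over all genes. Adjusted over the list alone, Cd68 of the macrophage list (2 tested members) rose. Mfge8 of the dendritic list (1 tested member) and Acta1 of the muscle list (6 tested members) fell. With so few members this adjustment is slight for Cd68 and none for Mfge8. The most abundant members of the fibroblast list were Fbln1 (289 ± 15.9 and 309 ± 73.6 CPM) and Dcn (48.1 ± 19.6 and 68 ± 17.8 CPM), while the collagen gene Col1a1 had 4.16 ± 0.48 CPM untreated and 29, 4.7 and 3.7 CPM in ibuprofen replicates 1, 2 and 3. The mean of the fibroblast list relative to the untreated mean was 1.194 log2 units in ibuprofen replicate 1, against -0.168 and -0.138 in the others. The fibroblast list had a median of 0.353 and a camera adjusted p of 0.535 in limma, the muscle list 0.019 and 0.231. The most abundant muscle-list gene, Tagln, had 6.53 ± 0.596 and 6.95 ± 0.476 CPM, and the one with the smallest p, Acta1, 2.58 ± 1.55 and 0.433 ± 0.115 CPM. The endothelial gene Pecam1 had 11.5 ± 1.02 and 14.4 ± 1.98 CPM. Mbp, in the Schwann list, had 85.7 ± 6.81 and 86.7 ± 7.28 CPM, and Mfge8, in the dendritic list, 67.3 ± 10.3 and 47.8 ± 4.33 CPM. Among immune genes Cd52 had 6.23 ± 0.55 and 5.33 ± 1.36 CPM, Cd68 5.2 ± 1.39 and 8.59 ± 0.736 CPM, Kit 4 ± 0.54 and 8.48 ± 6.98 CPM, Lck 0.983 ± 0.453 and 1.48 ± 1.02 CPM and Cd79a 0.716 ± 0.292 and 1.08 ± 0.75 CPM. The erythroid gene Alas2 had 1.22 ± 0.48 and 1.87 ± 0.586 CPM.

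All 6 libraries had high Xist, at 4770 ± 558 CPM untreated and 5280 ± 388 CPM with ibuprofen, and the summed Y-linked genes stayed at or below 0.4 CPM. Mitochondrially encoded protein genes took 1.61% ± 0.307 of the CPM untreated and 1.93% ± 0.159 with ibuprofen (exact two-sided permutation p = 0.2, smallest possible 0.1, adjusted 0.7 over 7 measures). The 50 most abundant genes took 18.3% ± 1.22 and 17.4% ± 0.361 (exact p = 0.3). In untreated replicate 1 they took 19.7%, against 17.1% to 17.8% in the other libraries. That library also stood apart in ribosomal RNA genes (2.4% against 1.54% to 1.65%) and protein-coding genes (84.8% against 86.6% to 87.2%). It had the fewest estimated reads, 6361297, and the fewest genes above 0, 24414. Libraries differed in how expression followed GC content. Spearman's rho across genes between transcript GC and a library's deviation from the mean of all libraries was 0.47, 0.19 and -0.28 in untreated replicates 1, 2 and 3. It was -0.25, -0.32 and -0.09 in ibuprofen replicates 1, 2 and 3. Genes are not independent replicates, so these values describe the libraries. The first principal component held 48.8% of the variance, with untreated replicates 1, 2 and 3 at -40.1, -20.2 and -2.54 and the ibuprofen replicates 1, 2 and 3 at 16.4, 11 and 35.6.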

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

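The GC content and gene length corrections were chosen after the data were seen. Of the 87 called genes, 0 changed sign under any alternative that tested them. At the filter of 5 CPM 77 of them were tested, and with any single ibuprofen library left out 82. All 87 had groups that did not overlap. Leaving out a library or changing the pseudocount, filter, library weights, shrinkage or block therefore could not change their sign. With no filter 52 genes were called, 29 higher and 23 lower, among 34431 tested, and with a filter at 5 CPM 33 were higher. Library weights gave 2462 calls, 1463 higher and 999 lower. With the replicate number as a block there were 434, 299 higher and 135 lower. The correlations of same-numbered libraries' deviations were 0, 0.08 and 0.15, and not every library correlated best with its own number, so the numbers do not pair the libraries. The GC correction gave 60 lower genes, and the GC and length correction 64. Leaving out single libraries gave 4 to 456 calls, 3 to 276 higher and 1 to 180 lower. Fewer genes reach the filter of 5 CPM and more are tested with no filter; for the other changes in these counts the cause was not tested, apart from GC content and gene length for the calls lost without untreated replicate 1. With an estimated correlation 0 lists were called. The adjusted p was then 0.141 for the unfolded protein response, 0.423 for immediate-early and heat-shock genes and for NRF2, and 0.833 for cell cycle and cholesterol biosynthesis. The directional test of fry called 1 list, the unfolded protein response. Its adjusted p was 0.0651 for immediate-early and heat-shock genes and for NRF2, 0.606 for cell cycle and 0.533 for cholesterol biosynthesis. The mixed test of fry asks for change in either direction. Its adjusted p was 0.00784 for the unfolded protein response and for immediate-early and heat-shock genes. It was 0.0103 for PPAR, 0.026 for Wnt and mesenchymal genes, 0.0347 for basal squamous, Notch, NRF2 and p53 genes, and 0.0636 or higher for the others. With single libraries left out, the camera adjusted p ranged from 1.5e-12 to 0.721 for cell cycle, from 3.54e-06 to 0.0804 for cholesterol biosynthesis and from 0.0016 to 0.0537 for NRF2. It ranged from 1.12e-09 to 1.67e-07 for the unfolded protein response and from 2.58e-08 to 1.94e-05 for immediate-early and heat-shock genes. Hsph1, Scn3a and Greb1l stayed called under each of the 18 alternatives run on genes. DESeq2 and edgeR were planned for the case that counts were held, with a count test as an added alternative if whole reads could be recovered. The deposited values are scaled and rounded, not counts. The steps returned at least 99.82% of the values above 0 exactly, but DESeq2 and edgeR were not run on the estimated reads. These reads served only for depth and floors, so this alternative is missing. The calls thus rest on limma alone. At 6361297 to 8764370 reads per library, genes under about 1 CPM rest on few reads.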

Other observations

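The lists named here and every test below were chosen after the data were seen, except the test of cold-inducible genes, the split test of lists and the test without untreated replicate 1, whose predictions were written before their results. The ceiling of immediate-early genes and the clock lists in other splits were looked at only after the first results of those tests, and both made the reading more open. Among added lists, 9 of 9 tested epidermal cornification genes had positive fold changes, with a median of 0.93. The called members were the gap junction gene Gjb6 (1.5 ± 0.26) and the interleukin family gene Il1f5 (1.16 ± 0.21), and Gjb2 had 0.93 ± 0.19. Camera gave an adjusted p of 2.18e-07 in limma, and an adjusted p of 0.0486 with an estimated correlation. The list shares Krt1, Krt10 and Dsg1a with the fixed differentiation list but leaves out members of it with negative values, such as Tgm1 (-0.54 ± 0.14), Sprr2a3 (-0.56 ± 0.18), Tgm3 (-0.37 ± 0.16) and Cnfn (-0.36 ± 0.33). Caveolae genes had negative fold changes in 7 of 7 members, with Cav1 (-0.9 ± 0.13) and Cavin1 (-0.7 ± 0.13) called and an adjusted p of 0.0631 with an estimated correlation. The list of HSP90 and HSF1 machinery also holds mitochondrial chaperone genes, such as Hspd1 and Dnaja3. It was negative in 15 of 16 members, with Fkbp4 (-0.97 ± 0.14), Stip1 (-0.66 ± 0.1) and Dnaja3 (-0.6 ± 0.11) called. Its camera adjusted p was 0.0486 with an estimated correlation. The HSP90 gene Hsp90ab1 had -0.13 ± 0.11. ER folding and translocation genes were negative in 16 of 18, with Hyou1, Calr (-0.66 ± 0.11) and Dnajb11 (-0.82 ± 0.13) called and an adjusted p of 0.11 with an estimated correlation. Of 4 tested goblet and secretory genes 2 rose, Muc2 and Fcgbp (1.31 ± 0.22). Ribosome biogenesis genes were negative in 15 of 20, with a median of -0.16 and an adjusted p of 0.268 with an estimated correlation. Some members of these lists had been seen as called before the lists were written, so the counts and p-values are not independent evidence.

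With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real split called 87 genes and the highest of the others 3, and 1 of the 10 gave as many. For lists at the preset correlation, the real split called 5 and the highest of the others 11, and 8 of the 10 gave as many. Other groupings of these libraries thus gave as many called lists, so the number of preset list calls does not set the real grouping apart. By list, the real split had the smallest camera p for 3 lists. These were the unfolded protein response (1.07e-10, smallest other 0.000129), immediate-early and heat-shock genes (1.96e-08, 2.92e-06) and NRF2 (0.00374, 0.00597). For cell cycle 6 and for cholesterol biosynthesis 2 of the 9 other splits gave a smaller camera p. Each other split still places the treatment groups unevenly, and genes that vary together beyond the preset correlation were not separated from structure among the libraries.

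Of the heat-shock genes 3 of 7, and of the unfolded protein response members 3 of 18, fell with ibuprofen. The fixed lists that hold them lost their calls with an estimated correlation, at adjusted p of 0.423 and 0.141. As added lists, with an estimated correlation, the 7 heat-shock genes had a camera adjusted p of 0.0486 and the 14 immediate-early genes 0.174. At the preset correlation both were lower, with camera adjusted p of 4.81e-09 and 0.00407. Of the immediate-early genes 12 of 14 had negative fold changes, with a median of -0.13. Their library means were 9.57, 9.52 and 9.43 log2 units untreated and 9.28, 9.46 and 9.38 with ibuprofen for replicates 1, 2 and 3. Both lists were split from the fixed list after the data were seen and adjusted over the added lists only. They do not restore the lost call. GC content and gene length bias as the whole cause is argued against, since the median log2 fold change of the unfolded protein response members and heat-shock genes was -0.35 before and -0.45 after both trends were taken out. Stress of tissue dissociation stays open: heat-shock genes changed by -0.61 more than immediate-early genes (SE 0.1), but the median immediate-early gene lay above 99.4% of genes in the ibuprofen libraries, where a ceiling could hide a difference. Time of day at sampling may contribute, as clock output genes such as Tef (1.12 ± 0.21) and those of the opposite phase moved apart, with camera p of 0.000535 and 0.0113. With an estimated correlation both had an adjusted p of 0.167, only 1 of 11 and 0 of 6 members were called, and 3 other splits also had both lists past the threshold in opposite directions, so the test does not decide. Lower tissue temperature is also open, because Cirbp was higher by 2.67 standard errors and Rbm3 by 0.74, and an effect of ibuprofen itself or of an unknown batch cannot be told apart from these.

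Many of the genes that rose were long, with 42 of 50 above the median span of tested genes, though short ones such as Il1f5 and Gjb6 rose too and rho with span across all genes was 0.07; the excess itself was not tested. After the fitted trends on GC content, exonic length and genomic span were taken out, 42 of the 50 genes, or 84%, were still called in the same direction. Smooth trends of this kind thus do not account for most of these calls. Whether the excess of long genes remains among the corrected calls was not examined, so bias as its cause stays open. A longer gene could also collect more reads from unspliced RNA, which was not tested because the table does not separate introns from exons.

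The number of calls depended on single libraries, with 4 genes called without untreated replicate 1, 5 without untreated replicate 2 and 456 without untreated replicate 3. For untreated replicate 1, the test of GC content and gene length bias as the cause does not decide. After the same correction 114 genes were called in 6 libraries and 1 without untreated replicate 1, or 0.877%. Uncorrected calls also dropped to 23 without ibuprofen replicate 1 and 44 without ibuprofen replicate 3. Losing a library could thus give this result whatever the bias does. The higher ribosomal RNA share and lower depth of untreated replicate 1 were not tested as a cause. The other libraries were not tested this way, no biological explanation was tested, and the loss of a library from a group of 3 stays open.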
